A study of Mus musculus with 52 samples.

How the data were processed

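RNA-seq was measured in whole kidney, spleen and brain of female NZB/W-F1 and C57BL/6 mice of 1, 3 and 6 months, in 52 libraries (18 of kidney, 16 of spleen and 18 of brain). Per the labels' protocols the animals were perfused with buffered saline, total RNA was taken with TRIzol, and the libraries were made with the TruSeq RNA v2 kit, whose strand setting is not stated. Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.6, counted per gene with HTSeq and normalised with edgeR. The deposited tables, 1 per tissue, hold a signal of CPM scaled by trimmed-mean factors: per the labels the unit is CPM, but some column totals exceed what plain CPM allows, and the geometric mean of the totals is 1000000. The plan had assumed CPM, and values are printed as CPM on this deposited scale.

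Whole read counts were recovered from each deposited column within a tolerance of 0.01, for 100% of the values. They give depths of 6.52 to 17.5 in brain (median 12.0, in units of 1000000 reads), 5.46 to 16.8 in kidney (median 9.96) and 5.27 to 19.4 in spleen (median 9.15). A floor of 3 reads per library corresponds to 0.172 to 0.461 CPM in brain, 0.136 to 0.402 in kidney and 0.154 to 0.531 in spleen. Folds against a group with no read are bounds against this floor, and those against 1 to 3 reads carry 95% counting intervals. Intervals and floors cover counting error only.

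Genes were matched without version number to GENCODE vM21 (GRCm38, the assembly of mm10): 14448 of 14453 in kidney, 15115 of 15122 in spleen and 14888 of 14895 in brain. All positions are on that build. In kidney, 3 counter totals in the table (reads aligned to several places, ambiguous or in no gene), together 20.8 to 29.9% of the reads, were left out. The tables hold no gene of the Y chromosome.

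Each tissue was fitted on its own with limma 3.58.1 (R 4.3.3) as trended moderation on log2(CPM + 0.5), with a mean for each of the 6 groups, over genes with a CPM of at least 1 in as many libraries as the smallest group holds: 14373 in kidney, 15122 in spleen and 14895 in brain. The comparisons were the strains at each age, 3 against 1 month and 6 against 3 months in NZB/W-F1, 6 against 3 months in C57BL/6, and the strain by age interaction over the last interval. Genes past the threshold in 1 direction at all 3 ages, or in all 3 tissues at 6 months, were counted as well. The threshold was a Benjamini-Hochberg adjusted p of 0.05 in two-sided tests, and the same contrasts were run with the quasi-likelihood test of edgeR 4.0.16 on the recovered reads.

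Of 44 gene lists fixed in the plan, those with at least 5 members tested were used, 24 in kidney, 26 in spleen and 29 in brain. They were tested with camera at a correlation of 0.01, with camera at an estimated correlation and with fry. A list's member counts give those past the threshold over all genes and those with the p adjusted over the list alone.

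Genes are named by a rule: at an adjusted p under 0.05, with a mean of at least 5 CPM in a compared group and no overlap between the groups' libraries, those with the largest changes in each direction, 8 for the strains at 6 months, 6 for the interaction and for all 3 tissues, and 3 elsewhere. Predicted genes and antibody or T cell receptor segments were passed over. From each list up to 4 members with the smallest p could be named. For 2 genes that could be named, the results are not reported here. For each gene the share of its 31-base words found in a gene at another place was computed, and genes with 50% or more are given as uncertain. After their values were seen, Ndufs5 and Rpl26 were added for copies that rose where they fell.

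The alternatives were edgeR in place of limma, median-of-ratios scaling, no filter, only the compared groups in the fit, a pseudocount of 0.1, a block for replicate number and leaving out each replicate. Where that leaves 1 library in a group, it is assumed to vary like the others. Comparisons, lists, the named-gene rule and these alternatives were chosen before the data were examined. Chosen after seeing values were the adipocyte and pancreatic enzyme sets, leaving out 2 spleen libraries or the animal with few Xist reads, and a crossed numbering of spleen replicates. In kidney same-number NZB/W-F1 libraries of 3 and 1 months had correlated residuals (r 0.20 to 0.53, 3 pairs), known from the data alone. The all-group block (41 genes against 43) cannot test these pairs, as strains at 1 month had mean r -0.27.

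Simulated data at these depths had 200 changed genes. Limma found 90.9%, 57.6% and 98.5% of 4-fold changes, and 50.7%, 4.48% and 82.1% of 2-fold changes, in the 6-month strain comparison of kidney, spleen and brain, and for the interaction 72.7%, 33.3% and 95.5% of 4-fold changes. The 1 list that was moved passed in each tissue, with 0 of 20 others. In real kidneys, though, 33 of 100 drawn assignments of age gave at least the real 13 interaction lists.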

Results

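The series follows female NZB/W-F1 mice, hybrids of the New Zealand Black and New Zealand White strains that develop a lupus-like disease with nephritis, and asks how expression changes in kidney, spleen and brain as the disease appears. Age-matched female C57BL/6 mice were the controls at 1, 3 and 6 months. Each group held 3 animals per tissue, except the C57BL/6 spleens at 3 and 6 months with 2 each. Expression is given in CPM (counts divided by library size) on the deposited scale, changes as log2 fold changes from limma with their standard errors (SE), and group levels as mean ± SD. For a gene list, the median is that of the log2 fold changes of its tested members and the adjusted p is that of camera, with a preset correlation unless an estimated one is named. Genes named as changed had no overlap between the libraries of the groups compared.

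**Figure D1:**
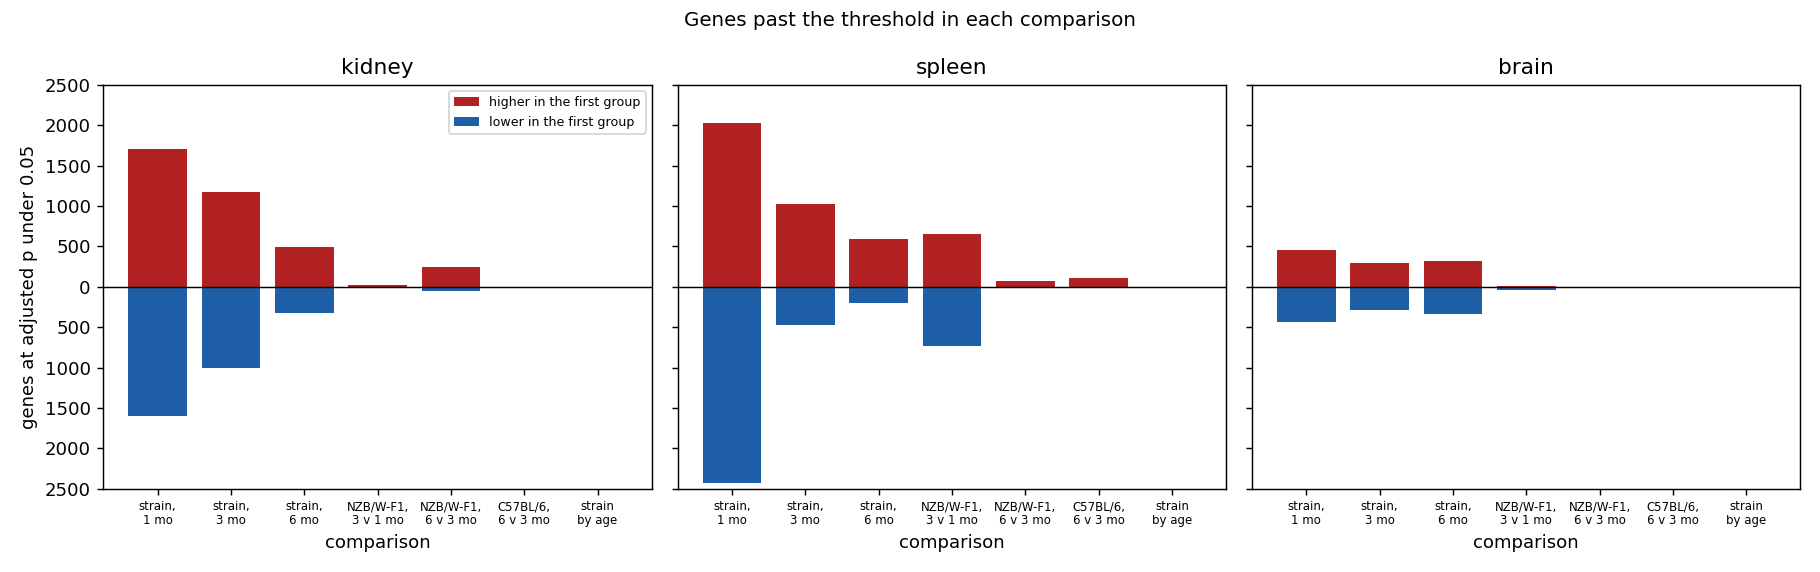
Number of genes at an adjusted p under 0.05 (limma) in each comparison of kidney, spleen and brain, drawn upwards when higher and downwards when lower in the first group, where strain comparisons set NZB/W-F1 against C57BL/6. In all 3 tissues the 1-month strain comparison (batch not separated) gave the longest bars, up to 4449 genes in spleen. Strain by age from 3 to 6 months gave 0.

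At 6 months, when the labels place the hybrids at the nephritic stage, NZB/W-F1 kidneys held more RNA of antibody, macrophage, B cell, cell cycle and kidney injury genes than C57BL/6 kidneys. Ighg2c (ENSMUSG00000076612, chromosome 12, 113285325 to 113288932), the constant region of IgG2c heavy chains, averaged 101 ± 43.8 CPM against 4.65 ± 3.34 CPM (n = 3 each, log2 fold change 4.49, SE 0.65, adjusted p = 2.6e-04). Ighg3 (ENSMUSG00000076615, chromosome 12, 113356224 to 113361232), that of IgG3, averaged 30.9 ± 12.3 CPM against 0.496 ± 0.422 CPM (log2 fold change 4.97, SE 0.44, adjusted p = 1.0e-06). Ighm of IgM and Ighg2b of IgG2b rose as well, to log2 fold changes of 1.58 and 2.47 (adjusted p = 0.003 and 0.0038). Havcr1 (ENSMUSG00000040405, chromosome 11, 46735080 to 46779578), the tubule injury marker KIM-1, averaged 90.1 ± 74.3 CPM against 2.00 ± 1.11 CPM (log2 fold change 4.97, SE 0.47, adjusted p = 1.8e-06), a difference that was already present at 1 month. Of the immunoglobulin constant genes 6 of 9 rose (7 adjusted over the list alone, median 1.58, adjusted p = 2.1e-06, adjusted p = 0.15 with an estimated correlation).

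Among macrophage markers 4 of 18 rose (12 adjusted over the list alone, median 0.81, adjusted p = 2.1e-06, adjusted p = 0.47 with an estimated correlation). They were led by the integrin subunit Itgam with a log2 fold change of 1.98, the lipopolysaccharide co-receptor Cd14 with 1.55 and the lysozyme Lyz2 with 1.5 (adjusted p = 0.003, 0.0032 and 0.0059). B cell genes followed, of which 5 of 10 rose (8 adjusted over the list alone, median 1.16, adjusted p = 8.6e-05, adjusted p = 0.35 with an estimated correlation). Higher members were Cd22 (2.6, adjusted p = 6.7e-06) and Ms4a1 (2.01, adjusted p = 0.0033), an inhibitory receptor and the CD20 antigen. In the kidney injury list 5 of 22 rose (7 adjusted over the list alone, median 0.73, adjusted p = 2.1e-06, adjusted p = 0.35 with an estimated correlation). They included Tnfrsf12a, the receptor of the cytokine TWEAK, and Lcn2, the tubule stress protein lipocalin 2 (1.57 and 2.51, adjusted p = 0.0023 and 0.013). Of the cell cycle genes 5 of 24 rose (17 adjusted over the list alone, median 0.94, adjusted p = 7.2e-09, adjusted p = 0.47 with an estimated correlation), among them the proliferation antigen Mki67 (1.89, adjusted p = 0.017). The proximal tubule list went down, where 1 of 23 fell and 1 rose (3 adjusted over the list alone, median -0.36, adjusted p = 0.03, adjusted p = 0.76 with an estimated correlation). Lcn2 and Mki67 missed the threshold without NZB/W-F1 replicate 1 or 2, or C57BL/6 replicate 2 (adjusted p 0.06 to 0.11). The proximal tubule list missed it without NZB/W-F1 replicate 3, or C57BL/6 replicate 2 (adjusted p 0.068 to 0.096). Mki67 missed it with only these libraries fitted (adjusted p = 0.068). The proximal tubule list missed it in edgeR (adjusted p = 0.075).

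Other large strain differences in the 6-month kidney were those of single genes. Angptl7 (ENSMUSG00000028989, chromosome 4, 148495183 to 148500460), an angiopoietin-like secreted protein, was higher at 189.8 ± 35.2 CPM against 1.07 ± 0.602 CPM (log2 fold change 6.99, SE 0.36, adjusted p = 9.5e-10). Serpina6 (ENSMUSG00000060807, chromosome 12, 103646630 to 103657212), the corticosteroid-binding globulin, was higher too (log2 fold change 4.36, SE 0.43, adjusted p = 2.9e-06). Angptl7 lies inside Mtor on the opposite strand, and the labels do not state whether the libraries kept the strand. Akr1c21 (ENSMUSG00000021207, chromosome 13, 4574075 to 4586541), a hydroxysteroid dehydrogenase, was lower at 3.81 ± 0.939 CPM against 599 ± 41.8 CPM (log2 fold change -7.14, SE 0.28, adjusted p = 4.8e-11). So was Atp4a (ENSMUSG00000005553, chromosome 7, 30712209 to 30725534), a subunit of the proton pump that acidifies the stomach (log2 fold change -4.37, SE 0.35, adjusted p = 2.8e-07). Trim12a (ENSMUSG00000066258, chromosome 7, 104299894 to 104315466), of the family of tripartite-motif restriction factors, had 1 read over the 3 NZB/W-F1 libraries against 467 reads (464-fold, interval 82.8 to 18350 by counting). Also lower were Gabra3, a GABA receptor subunit on chromosome X, Clec2h, a C-type lectin-like gene, and Ugt1a7c, a glucuronosyltransferase that shares exons with its Ugt1a neighbours, with log2 fold changes of -4.02, -3.68 and -3.58. The values of 5 further genes are uncertain, since 50% or more of the 31-base words of the ribosomal protein copy Rps3a3 (6.43), the enolase copy Eno1b (5.74), the tropomyosin-related Tpm3-rs7 (5.09) and the methyltransferase-like Mettl7a2 (-5.80) occur in another gene, and Methig1 (-3.94) overlaps Mettl7a2.

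In total 818 of 14373 genes passed limma's threshold in the 6-month kidney comparison, 498 higher and 320 lower in NZB/W-F1, and edgeR gave 812. The camera test passed 10 of 24 lists, 0 with an estimated correlation, and fry passed 6. Summed over 9 adipocyte genes, a set chosen after the data were seen, the 6-month kidneys held 366 to 706 CPM in NZB/W-F1 and 959 to 2532 CPM in C57BL/6. The 818 became 488 without C57BL/6 replicate 2.

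From 3 months (before autoimmunity) to 6 (nephritic), NZB/W-F1 kidneys gained antibody, macrophage and B cell RNA, with batch not separated from age. Of immunoglobulin constant genes 9 of 9 rose (9 adjusted over the list alone, median 3.30, adjusted p = 2.0e-18, adjusted p = 0.0017 with an estimated correlation). Ighg2c rose from 1.75 ± 2.09 CPM to 101 ± 43.8 CPM (log2 fold change 5.86, SE 0.65, adjusted p = 2.1e-04). Ighg2b (ENSMUSG00000076613, chromosome 12, 113302965 to 113307933) rose from 0.491 ± 0.392 CPM to 38.9 ± 27.1 CPM (log2 fold change 5.12, SE 0.48, adjusted p = 5.4e-05). Ighg3 rose by a log2 fold change of 4.28 and the kappa light chain Igkc by 3.80 (adjusted p = 1.0e-04 and 5.4e-05). Of the macrophage markers 12 of 18 rose (15 adjusted over the list alone, median 1.43, adjusted p = 7.2e-15, adjusted p = 0.083 with an estimated correlation). Itgam stood at 2.63, the F4/80 antigen Adgre1 at 1.40 (adjusted p = 0.0018 and 0.002). Of the plasma cell genes 4 of 14 rose (6 adjusted over the list alone, median 0.41, adjusted p = 1.0e-04, adjusted p = 0.083 with an estimated correlation). Jchain, which joins antibody multimers, stood at 3.60 (adjusted p = 9.5e-05). Of the B cell genes 6 of 10 rose (8 adjusted over the list alone, median 1.36, adjusted p = 8.9e-08, adjusted p = 0.083 with an estimated correlation). The adipocyte genes summed to 2110, 1600 and 342 CPM at 3 months and 366, 568 and 706 CPM at 6. Itgam missed the threshold with only these libraries fitted (adjusted p = 0.06).

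Injury and inflammation genes moved with them over the same interval. In the kidney injury list 4 of 22 rose (10 adjusted over the list alone, median 0.88, adjusted p = 1.0e-07, adjusted p = 0.12 with an estimated correlation), with lipocalin 2, Lcn2 (3.04, adjusted p = 0.011). In the cell cycle list 6 of 24 rose (19 adjusted over the list alone, median 1.27, adjusted p = 2.0e-13, adjusted p = 0.17 with an estimated correlation). In the chemokine list 2 of 15 rose (13 adjusted over the list alone, median 1.02, adjusted p = 1.8e-07, adjusted p = 0.083 with an estimated correlation). Among interferon-stimulated genes 2 of 34 rose (9 adjusted over the list alone, median 0.59, adjusted p = 1.4e-09, adjusted p = 0.24 with an estimated correlation). Of the proximal tubule genes 0 of 23 fell (5 adjusted over the list alone, median -0.63, adjusted p = 2.6e-05, adjusted p = 0.24 with an estimated correlation). Clec2h fell (log2 fold change -1.97, SE 0.43, adjusted p = 0.027). So did the coagulation cofactor Proz (ENSMUSG00000031445, chromosome 8, 13060914 to 13076026) (log2 fold change -1.5, SE 0.29, adjusted p = 0.012) and the potassium channel subunit Kcne1l (ENSMUSG00000090122) (log2 fold change -1.33, SE 0.30, adjusted p = 0.031). Lcn2 missed the threshold without 6-month replicate 1, or 3-month replicate 2 (adjusted p = 0.057). Clec2h and Proz missed it without 6-month replicate 1, or 3-month replicate 2 or 3 (adjusted p 0.061 to 0.1). Kcne1l missed it without 6-month replicate 1 or 3, or 3-month replicate 1 or 2 (adjusted p 0.075 to 0.15). Clec2h, Proz and Kcne1l missed it with only these libraries fitted (adjusted p 0.06 to 0.12).

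Between 3 and 6 months 301 of 14373 genes passed in NZB/W-F1 kidneys, 248 higher and 53 lower at 6 months, 296 in edgeR and 78 when only these 6 libraries were fitted. Camera passed 18 of 24 lists, 1 with an estimated correlation (immunoglobulin constant), and fry passed 10. The 301 became 148 and 189 without 6-month replicates 1 and 2 and 167, 108 and 130 without 3-month replicates 1, 2 and 3.

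In C57BL/6 kidneys, between 3 and 6 months, 1 gene passed the threshold, the kappa variable segment Igkv10-96, which was higher at 6 months and is named here after its value was seen, against 0 in edgeR and 2359 at an unadjusted p under 0.05. Ighg2c averaged 1.0 ± 0.891 CPM and 4.65 ± 3.34 CPM there, and Itgam 1.55 ± 0.392 CPM and 1.57 ± 0.0550 CPM. The immunoglobulin constant list rose in C57BL/6 as well, although 0 of 9 rose (6 adjusted over the list alone, median 1.26, adjusted p = 1.6e-04, adjusted p = 0.31 with an estimated correlation). The difference between the strains in this change was tested as an interaction. Limma passed 0 genes for it and edgeR 0, with 3719 at an unadjusted p under 0.05. By list, camera passed 13 of 24 for the interaction, 0 with an estimated correlation, and fry passed 5. The interaction medians were 2.17 for immunoglobulin constant genes and 1.33 for B cell genes (adjusted p = 1.6e-06 and 4.7e-05), and 0.1 and 0.34 were the adjusted p values with an estimated correlation. The 1 became 0 and 0 without 6-month replicates 1 and 2 and 0 and 1780 without 3-month replicates 2 and 3. For the interaction the 0 became 7, 1 and 47 without NZB/W-F1 6-month replicates 1, 2 and 3, 1 without NZB/W-F1 3-month replicate 1 and 2839 without C57BL/6 3-month replicate 3.

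**Figure D2:**
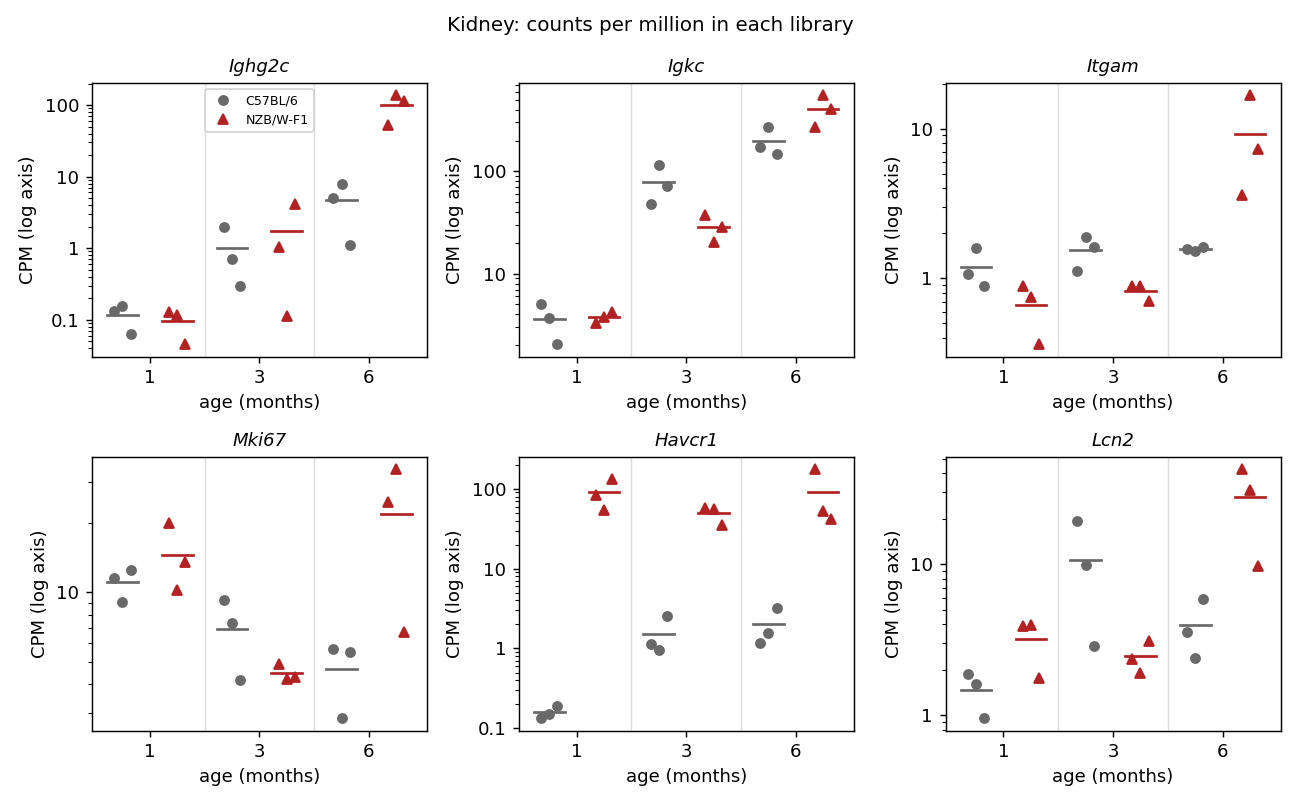
CPM (log axis) of Ighg2c, Igkc, Itgam, Mki67, Havcr1 and Lcn2 in each kidney library by age in months, as circles for C57BL/6 and triangles for NZB/W-F1, with a bar at each group mean. Ighg2c and Itgam stand highest in the 6-month NZB/W-F1 group, at means of 101 ± 43.8 CPM and 9.19 ± 6.76 CPM, while Havcr1 separates the strains at each age.

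**Figure D3:**
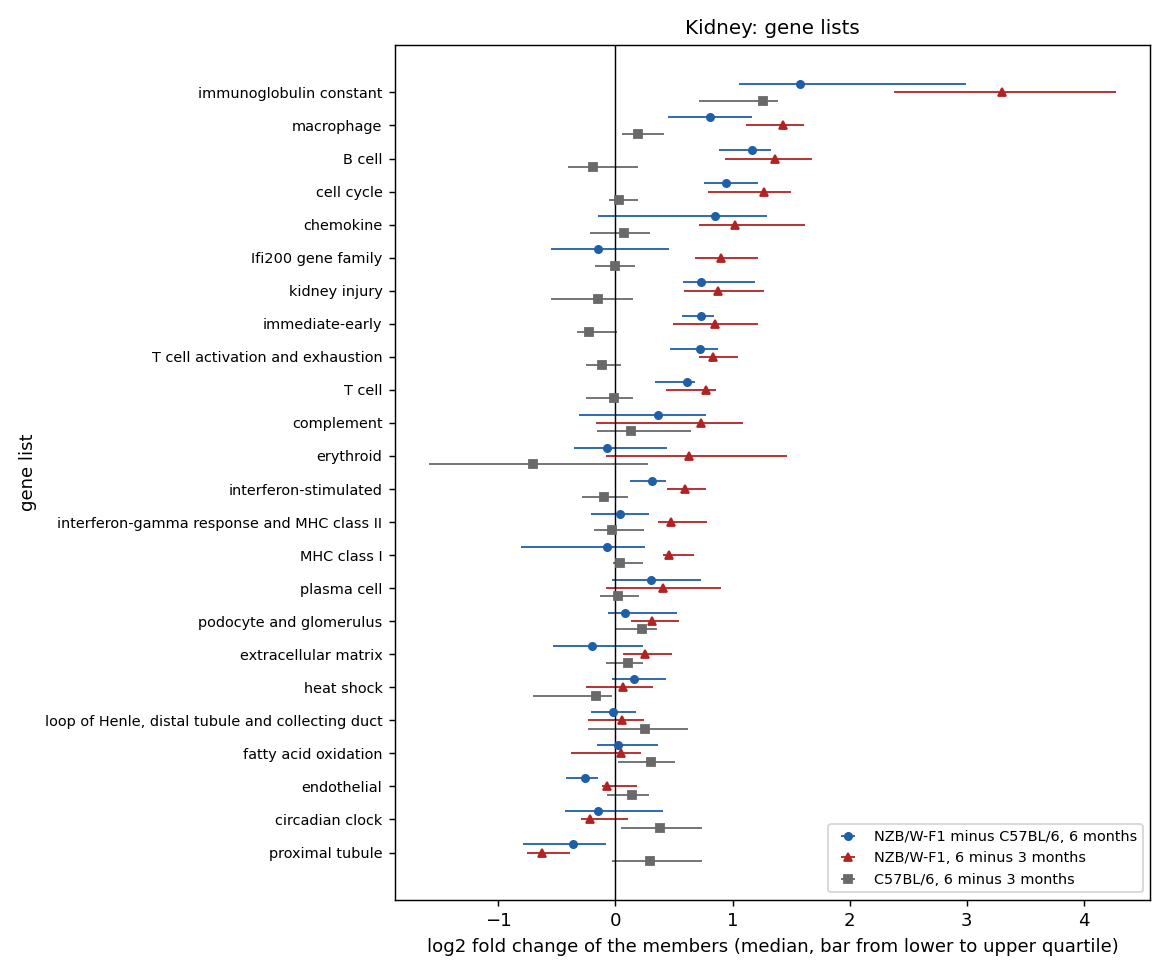
Median log2 fold change of the tested members of each kidney gene list, with bars from the lower to the upper quartile, for the strain comparison at 6 months (circles) and the change from 3 to 6 months in NZB/W-F1 (triangles) and in C57BL/6 (squares). Immunoglobulin constant genes had the largest medians, 1.58, 3.30 and 1.26 in that order.

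The strains already differed in kidney at 1 month, in single genes and in the heat shock list, with batch not separated from strain. Akr1c18 (ENSMUSG00000021214, chromosome 13, 4132615 to 4150654), which inactivates progesterone, averaged 514 ± 561 CPM against 0.989 ± 0.469 CPM in NZB/W-F1 and C57BL/6 (log2 fold change 7.91, SE 0.61, adjusted p = 1.4e-07). Havcr1 averaged 90.5 ± 40.1 CPM against 0.160 ± 0.0296 CPM (log2 fold change 7.01, SE 0.47, adjusted p = 2.5e-08). Angptl7 was higher (7.03) and Akr1c21 lower (-6.29, 3.30 ± 1.44 CPM against 279 ± 27.7 CPM). Trim12a showed 1 read against 543 (707-fold, interval 126 to 27990), while Mettl7a2 (-5.35) is uncertain for its copies. Heat shock genes were the 1 list that passed, where 4 of 13 rose (7 adjusted over the list alone, median 0.66, adjusted p = 0.0086, adjusted p = 0.94 with an estimated correlation). Among them was the chaperone Hspa5 (1.65, adjusted p = 2.4e-04). In this comparison 3310 genes passed, 1711 higher and 1599 lower in NZB/W-F1, 3324 in edgeR and 2197 with only these libraries fitted. The 3310 became 2187 without NZB/W-F1 replicate 2 and 2090 without C57BL/6 replicate 2.

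At 3 months interferon and MHC lists were lower and the fatty acid oxidation list higher in NZB/W-F1 than C57BL/6 kidneys (camera, preset correlation). The C57BL/6 group was split: the chi-square per gene against counting error was 6.29 between replicates 1 and 2, and 42.9 and 35.7 between these and replicate 3, against 19.4 to 43.2 within NZB/W-F1. Lcn2 held 19.4, 9.85 and 2.89 CPM in C57BL/6 replicates 1, 2 and 3, and the injury gene Krt20 (-3.06, adjusted p = 0.0082) was lower in NZB/W-F1. Of interferon-stimulated genes 5 of 34 fell (5 adjusted over the list alone, median -0.41, adjusted p = 0.0023, adjusted p = 0.88 with an estimated correlation), led by the antiviral factor Samd9l (log2 fold change -1.37, SE 0.13, adjusted p = 1.3e-06). MHC class I genes split, in that 6 of 13 fell and 1 rose (6 adjusted over the list alone, median -0.44, adjusted p = 0.0057, adjusted p = 0.88 with an estimated correlation), with H2-Q7 and H2-Q6 at -2.21 and -1.97 and H2-T24 at 1.31. In the Ifi200 family 4 of 10 fell and 1 rose (6 adjusted over the list alone, median -0.94, adjusted p = 0.0075, adjusted p = 0.88 with an estimated correlation). Ifi202b, an interferon-inducible DNA-binding protein within a lupus susceptibility region of New Zealand Black mice, had 1 read in C57BL/6 against 125 (90.4-fold, interval 15.9 to 3597, adjusted p = 9.9e-05), and Mndal was lower (-1.68, adjusted p = 0.0013). Of the fatty acid oxidation genes 6 of 23 rose (6 adjusted over the list alone, median 0.43, adjusted p = 0.0075, adjusted p = 0.88 with an estimated correlation). The largest single changes were those of Angptl7 (7.38), Akr1c21 (-6.88) and Trim12a (1 read against 484, 669.5-fold, interval 119.6 to 26500), besides Eno1b (6.41), Rps3a3 (5.37) and Mettl7a2 (-6.41), which are uncertain. Camera passed 7 lists, 0 with an estimated correlation, and fry 0. In total 2177 genes passed, 1177 higher and 1000 lower in NZB/W-F1, 1856 in edgeR and 596 with only these libraries fitted. The 2177 became 921 without NZB/W-F1 replicate 2 and 809, 815 and 4218 without C57BL/6 replicates 1, 2 and 3. The interferon-stimulated, MHC class I and Ifi200 lists missed the threshold without C57BL/6 replicate 1 (adjusted p 0.064 to 0.075). Fatty acid oxidation missed it without C57BL/6 replicate 1 or 2 (adjusted p 0.1 to 0.11).

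From 1 to 3 months the cell cycle list fell and antibody genes rose in NZB/W-F1 kidneys. In the cell cycle list 0 of 24 fell (16 adjusted over the list alone, median -1.04, adjusted p = 6.3e-15, adjusted p = 0.46 with an estimated correlation). Igha (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236), the IgA heavy chain, rose from 3.5 ± 3.38 CPM to 30.9 ± 8.54 CPM (log2 fold change 3.25, SE 0.44, adjusted p = 0.0025) and Igkc by 2.73 (adjusted p = 0.0017). In their list 2 of 9 rose (3 adjusted over the list alone, median 0.97, adjusted p = 2.9e-05, adjusted p = 0.3 with an estimated correlation). Arsi (ENSMUSG00000036412), an arylsulfatase, fell (log2 fold change -3.09, SE 0.56, adjusted p = 0.024). Serpina6 fell from 328 ± 112 CPM to 49.7 ± 17.4 CPM (log2 fold change -2.70, SE 0.43, adjusted p = 0.0088), and the elastin gene Eln (ENSMUSG00000029675) fell too (log2 fold change -2.23, SE 0.44, adjusted p = 0.042). The cytochromes Cyp2a4 (3.25) and Cyp2a5 (3.06) rose and are uncertain, as most words of each occur in another gene. In C57BL/6 Igha averaged 1.17 ± 0.270 CPM at 1 month and 82.3 ± 32.3 CPM at 3 months. Camera passed 11 lists here, 0 with an estimated correlation, and fry 1, immunoglobulin constant. In all 43 genes passed, 26 higher and 17 lower at 3 months, 38 in edgeR and 0 with only these 6 libraries fitted. The 43 became 27, 18 and 17 without 3-month replicates 1, 2 and 3 and 25, 17 and 227 without 1-month replicates 1, 2 and 3. Arsi missed the threshold without 3-month replicate 2 or 3, or 1-month replicate 1 or 2 (adjusted p 0.077 to 0.17). Serpina6 missed it without 3-month replicate 2 or 3, or 1-month replicate 2 (adjusted p 0.055 to 0.076). Eln missed it without 3-month replicate 1, 2 or 3, or 1-month replicate 1 or 2 (adjusted p 0.064 to 0.23). Igha, Igkc, Arsi, Serpina6, Eln, Cyp2a4 and Cyp2a5 missed it with only these libraries fitted (adjusted p 0.081 to 0.49). Serpina6 missed it with a pseudocount of 0.1 (adjusted p = 0.07). In kidney 382 genes differed between the strains in 1 direction at all 3 ages, 238 higher and 144 lower in NZB/W-F1, where 4.85 and 2.48 would be expected of independent lists of the same lengths.

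At 6 months NZB/W-F1 spleens held more RNA of plasma cell, immunoglobulin constant, germinal centre and platelet lists than C57BL/6 spleens. Ighg2c averaged 6443 ± 57.6 CPM against 554 ± 73.1 CPM (n = 3 and 2, log2 fold change 3.55, SE 0.35, adjusted p = 2.0e-05). Ighg3 averaged 9797 ± 6267 CPM against 236 ± 1.67 CPM (log2 fold change 5.17, SE 0.64, adjusted p = 1.4e-04). Ighe, the IgE heavy chain, rose by 3.75 and Ighg2b by 1.77 (adjusted p = 0.0018 and 5.8e-04). Of the immunoglobulin constant genes 8 of 12 rose (8 adjusted over the list alone, median 1.94, adjusted p = 4.6e-09, adjusted p = 0.0075 with an estimated correlation). Of the plasma cell genes 12 of 15 rose (14 adjusted over the list alone, median 1.52, adjusted p = 3.4e-20, adjusted p = 0.0075 with an estimated correlation). Mzb1 stood at 1.74 and the plasma cell transcription factor Xbp1 at 1.51 (adjusted p = 1.5e-04 and 9.7e-04). In the list of germinal centre and follicular helper T cell genes 8 of 18 rose (11 adjusted over the list alone, median 1.31, adjusted p = 1.5e-08, adjusted p = 0.39 with an estimated correlation). Higher were the B cell positioning receptor S1pr2 and the inhibitory receptor Pdcd1 (1.98 and 1.83, adjusted p = 0.0011 and 0.003).

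Platelet and megakaryocyte genes were higher as a group, where 8 of 11 rose (10 adjusted over the list alone, median 1.89, adjusted p = 2.1e-11, adjusted p = 0.32 with an estimated correlation). The integrin subunit Itgb3 (1.89, adjusted p = 0.0036) was among them. Red pulp macrophage and iron genes were lower, where 2 of 15 fell (2 adjusted over the list alone, median -0.52, adjusted p = 0.0052, adjusted p = 0.81 with an estimated correlation). The erythroid and neutrophil lists were lower too (median -1.51, adjusted p = 0.0016 and 0.81 with an estimated correlation, and median -1.11, adjusted p = 5.3e-04 and 0.81 with an estimated correlation). Itgb3 and the erythroid list missed the threshold without C57BL/6 replicate 1 (adjusted p = 0.1). The red pulp macrophage and iron list and the neutrophil list missed it without C57BL/6 replicate 2 (adjusted p 0.099 to 0.12). The erythroid list missed it without NZB/W-F1 replicate 3 (adjusted p = 0.24).

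Among the largest single differences of the 6-month spleen, Ifi202b (ENSMUSG00000026535, chromosome 1, 173962568 to 173982744) averaged 51.3 ± 23.9 CPM in NZB/W-F1 and had no read in C57BL/6, at least 124-fold higher against a floor of 3 reads per library. The neuropeptide gene Npy (ENSMUSG00000029819, chromosome 6, 49822710 to 49829507) averaged 46.0 ± 5.83 CPM in NZB/W-F1, and C57BL/6 had 1 read (703-fold, interval 126 to 27770). The phospholipase D family gene Pld5 (ENSMUSG00000055214) averaged 17.8 ± 4.98 CPM against 1 read (264-fold, interval 47.2 to 10460). Pld5 overlaps Rbm8a2 on the same strand. Chil3 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), a chitinase-like macrophage protein, had no read in NZB/W-F1 and 232 ± 86.9 CPM in C57BL/6, at least 772-fold lower. Trim12a had 3 reads against 1219 (811-fold, interval 277 to 3940) and Eps8l1 (ENSMUSG00000006154), related to an epidermal growth factor receptor substrate, 3 against 343 (228-fold, interval 77.5 to 1113). Gabra3 (-5.29) and the vomeronasal receptor gene Vmn2r97 (ENSMUSG00000091491) (-4.32) were lower as well. Copies leave Rps3a3 (6.06), Eno1b (828 reads against 2), Tpm3-rs7 (5.13), Trim5 (-4.48), the haemoglobin gene Hba-a2 (-8.54) and the eosinophil ribonuclease Ear1 (-4.04) uncertain. In total 796 of 15122 genes passed in the 6-month spleen, 598 higher and 198 lower in NZB/W-F1, 715 in edgeR and 517 with only these libraries fitted. Camera passed 10 of 26 lists, 2 with an estimated correlation (plasma cell and immunoglobulin constant), and fry 4. The 796 became 392 without C57BL/6 replicate 1. Ear1 missed the threshold without NZB/W-F1 replicate 1 or 2, or C57BL/6 replicate 1 or 2 (adjusted p 0.056 to 0.24). Ear1 missed it in edgeR (adjusted p = 0.11) and with a pseudocount of 0.1 (adjusted p = 0.096).

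**Figure D4:**
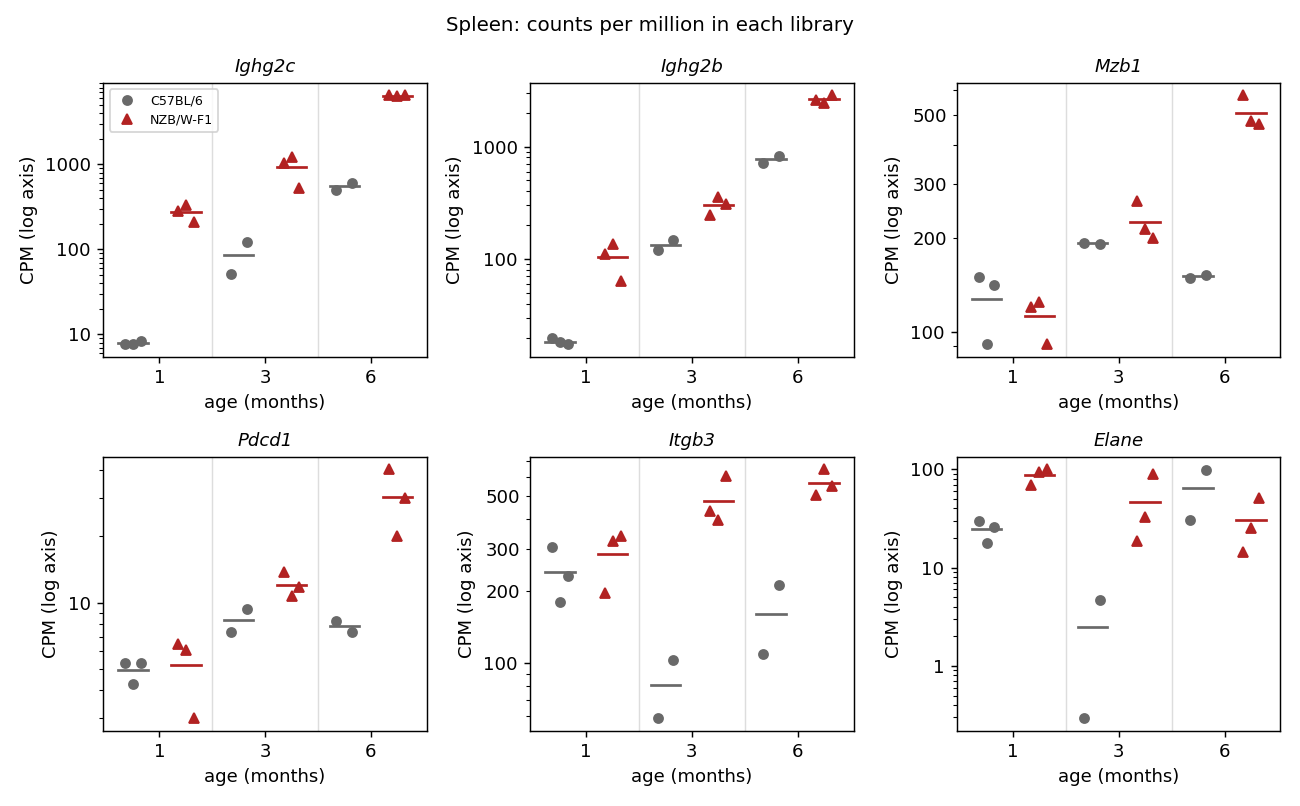
CPM (log axis) of Ighg2c, Ighg2b, Mzb1, Pdcd1, Itgb3 and Elane in each spleen library by age in months, as circles for C57BL/6 and triangles for NZB/W-F1, with a bar at each group mean. Ighg2c reached 6443 ± 57.6 CPM in 6-month NZB/W-F1 spleens, while the neutrophil elastase gene Elane was lowest in 3-month C57BL/6 spleens at 2.46 ± 3.07 CPM.

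From 3 to 6 months NZB/W-F1 spleens gained plasma cell and antibody RNA. Of the plasma cell genes 5 of 15 rose (13 adjusted over the list alone, median 1.09, adjusted p = 1.5e-29, adjusted p = 8.1e-04 with an estimated correlation), with the secretory factor Creld2 (1.35, adjusted p = 0.0072). In the immunoglobulin constant list 4 of 12 rose (8 adjusted over the list alone, median 1.56, adjusted p = 1.3e-17, adjusted p = 8.1e-04 with an estimated correlation). Ighg2b rose from 304 ± 53.7 CPM to 2631 ± 209 CPM (log2 fold change 3.12, SE 0.23, adjusted p = 3.7e-05). Ighg2c rose from 934 ± 359 CPM to 6443 ± 57.6 CPM (log2 fold change 2.87, SE 0.32, adjusted p = 8.5e-04), against 86.8 ± 50 CPM and 554 ± 73.1 CPM for Ighg2c in C57BL/6 at the same ages. Cxcl14 (ENSMUSG00000021508, chromosome 13, 56288643 to 56296551), a tissue chemokine, rose from 0.522 ± 0.231 CPM to 12.2 ± 3.62 CPM (log2 fold change 3.62, SE 0.47, adjusted p = 0.0034). In the T cell list 2 of 18 fell (4 adjusted over the list alone, median -0.37, adjusted p = 1.7e-09, adjusted p = 0.39 with an estimated correlation). They were both chains of the CD8 co-receptor, Cd8a (-1.43, adjusted p = 0.033) and Cd8b1 (-1.60, adjusted p = 0.048). The neuropeptide receptor gene Vipr1 (ENSMUSG00000032528, chromosome 9, 121642716 to 121672954) fell from 27.8 ± 7.33 CPM to 8.21 ± 4.53 CPM (log2 fold change -1.83, SE 0.38, adjusted p = 0.047) and Lrrc75b (ENSMUSG00000046807) fell too (log2 fold change -1.75, SE 0.35, adjusted p = 0.042). In the germinal centre list 1 of 18 rose (6 adjusted over the list alone, median 0.77, adjusted p = 5.3e-09, adjusted p = 0.28 with an estimated correlation). Cd8a missed the threshold without 3-month replicate 1 or 3 (adjusted p 0.12 to 0.13). Cd8b1, Vipr1 and Lrrc75b missed it without 6-month replicate 2 or 3, or 3-month replicate 1, 2 or 3 (adjusted p 0.055 to 0.2). Creld2, Ighg2c, Cd8a, Cd8b1, Vipr1 and Lrrc75b missed it with only these libraries fitted (adjusted p 0.069 to 0.51). Cd8b1, Vipr1 and Lrrc75b missed it in edgeR (adjusted p 0.069 to 0.076). Cxcl14, Cd8b1, Vipr1 and Lrrc75b missed it with a pseudocount of 0.1 (adjusted p 0.053 to 0.07). Lrrc75b missed it with a block for replicate number (adjusted p = 0.0502).

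Between 3 and 6 months 86 genes passed in NZB/W-F1 spleens, 78 higher and 8 lower at 6 months, 64 in edgeR, 54 with a pseudocount of 0.1 and 14 with only these 6 libraries fitted. Camera passed 17 lists, 2 with an estimated correlation, and fry passed 2, plasma cell and immunoglobulin constant in both cases. The 3-month NZB/W-F1 replicate 2 held 160100 CPM summed over 14 pancreatic enzyme genes, a set chosen after the data were seen, and the 1-month C57BL/6 replicate 1 held 40150. The 6-month NZB/W-F1 replicate 3 held 3784 and the 1-month C57BL/6 replicate 2 733, and the other spleens 13.6 to 49.2. Without the first 2 of these libraries, an alternative chosen after seeing the data, 39 genes passed for the change from 3 to 6 months. The 86 became 43 and 34 without 6-month replicates 2 and 3 and 46, 55 and 28 without 3-month replicates 1, 2 and 3.

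In C57BL/6 spleens neutrophil granule genes were higher at 6 than at 3 months, in a comparison of 2 against 2 libraries. Ngp (ENSMUSG00000032484, chromosome 9, 110419747 to 110423012), a neutrophil granule protein, averaged 672 ± 404 CPM against 31 ± 41.9 CPM (log2 fold change 5.85, SE 1.25, adjusted p = 0.049). Lcn2 (ENSMUSG00000026822, chromosome 2, 32384633 to 32388252) averaged 154 ± 88.5 CPM against 4.89 ± 6.70 CPM (log2 fold change 5.79, SE 1.10, adjusted p = 0.04). Ltf (ENSMUSG00000032496), lactotransferrin, averaged 355 ± 218 CPM against 16.5 ± 22.5 CPM (log2 fold change 5.74, SE 1.20, adjusted p = 0.048). Il5ra (ENSMUSG00000005364, chromosome 6, 106710357 to 106749037), a cytokine receptor chain of eosinophils and B cells, fell from 31.6 ± 4.28 CPM to 11.7 ± 1.96 CPM (log2 fold change -1.39, SE 0.25, adjusted p = 0.039). In the neutrophil list 7 of 16 rose (15 adjusted over the list alone, median 4.4, adjusted p = 9.2e-16, adjusted p = 0.4 with an estimated correlation). In the T cell list 0 of 18 fell (15 adjusted over the list alone, median -1.05, adjusted p = 1.6e-09, adjusted p = 0.44 with an estimated correlation). Other cell types moved as well, with medians of 1.73 for red pulp macrophage and iron, 1.34 for endothelial, 1.23 for extracellular matrix, 1.11 for platelet, 1.01 for macrophage and -0.89 for B cell genes (adjusted p 1.9e-08 to 4.2e-05, and 0.4 to 0.44 with an estimated correlation). In all 117 genes passed, 115 higher and 2 lower at 6 months, 23 in edgeR, 188 with a pseudocount of 0.1, 0 with only these 4 libraries fitted and 430 with a block for replicate number. The 117 became 318 and 1 without 6-month replicates 1 and 2 and 0 and 43 without 3-month replicates 1 and 2. Ngp, Lcn2, Ltf, Il5ra and the platelet and megakaryocyte list missed the threshold without 3-month replicate 1 (adjusted p 0.076 to 0.37). Ngp missed it without 6-month replicate 1 (adjusted p = 0.051). Ngp, Lcn2, Ltf and Il5ra missed it without 6-month replicate 2 (adjusted p 0.63 to 0.72). Il5ra missed it without 3-month replicate 2 (adjusted p = 0.076). Ngp, Lcn2, Ltf and Il5ra missed it with only these libraries fitted (adjusted p 0.099 to 0.13) and in edgeR (adjusted p 0.052 to 0.11). The strain by age interaction over this interval gave 0 genes in limma, 0 in edgeR and 1521 at an unadjusted p under 0.05. Its largest list median was -5.01 for neutrophil genes (adjusted p = 1.4e-19 and adjusted p = 0.19 with an estimated correlation). For that interaction the 0 became 1 and 2 without NZB/W-F1 6-month replicates 1 and 2, 171 without NZB/W-F1 3-month replicate 1, 2 and 1 without C57BL/6 6-month replicates 1 and 2 and 14 without C57BL/6 3-month replicate 2.

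At 1 month cell cycle and erythroid genes were higher in NZB/W-F1 spleens. Of the cell cycle genes 25 of 25 rose (25 adjusted over the list alone, median 2.43, adjusted p = 1.6e-13, adjusted p = 0.63 with an estimated correlation). The transcription factor E2f1 stood at 2.39 (adjusted p = 0.002). Of the erythroid genes 12 of 18 rose and 1 fell (12 adjusted over the list alone, median 4.17, adjusted p = 4.7e-04, adjusted p = 0.63 with an estimated correlation). The exception among erythroid genes was Hba-a2 (-8.10), uncertain for its copies. B cell genes were lower, where 6 of 15 fell (8 adjusted over the list alone, median -0.83, adjusted p = 0.0028, adjusted p = 0.63 with an estimated correlation). Ighg2c was higher already at this age, at 273 ± 59.3 CPM against 7.93 ± 0.355 CPM (log2 fold change 5.0, SE 0.32, adjusted p = 1.8e-07). In the immunoglobulin constant list 5 of 12 rose and 1 fell (5 adjusted over the list alone, median 0.50, adjusted p = 0.013, adjusted p = 0.63 with an estimated correlation). Ifi202b averaged 34.6 ± 5.49 CPM against 1 read in C57BL/6 (836-fold, interval 149.6 to 33030). Rps3a3 (6.46) is uncertain. Chil3 had no read in NZB/W-F1 and 189.6 ± 85.1 CPM in C57BL/6 (at least 562-fold lower) and Trim12a was lower (0.150 ± 0.138 CPM against 105 ± 18.1 CPM, -7.35). Of 15122 genes 4449 passed, 2026 higher and 2423 lower in NZB/W-F1, and 4486 in edgeR. With median-of-ratios scaling in place of the deposited one the median log2 fold change of all genes moved from -0.16 to -0.04 and the split became 2527 higher and 1734 lower. Camera passed 15 lists, 0 with an estimated correlation, and fry 12. Without both libraries with pancreatic enzyme reads 2044 genes passed. The 4449 became 2057 and 2914 without NZB/W-F1 replicates 1 and 3 and 1864 and 2555 without C57BL/6 replicates 1 and 3.

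At 3 months platelet, neutrophil and plasma cell genes were higher in NZB/W-F1 than in C57BL/6 spleens, as were lists of other cell types. Of the platelet and megakaryocyte genes 10 of 11 rose (11 adjusted over the list alone, median 2.84, adjusted p = 1.3e-11, adjusted p = 0.43 with an estimated correlation). Gp6, a platelet glycoprotein, stood at 3.23 (adjusted p = 2.7e-04). Of the neutrophil genes 13 of 16 rose (14 adjusted over the list alone, median 3.56, adjusted p = 1.2e-08, adjusted p = 0.6 with an estimated correlation), with the elastase Elane at 4.25 (adjusted p = 0.0032). Of the plasma cell genes 9 of 15 rose (10 adjusted over the list alone, median 1.10, adjusted p = 4.1e-05, adjusted p = 0.43 with an estimated correlation). The medians were 1.19 for endothelial, 1.02 for extracellular matrix, 0.91 for red pulp macrophage and iron and 0.60 for complement genes, and -0.82, -0.60 and -1.43 for the B cell, T cell and erythroid lists, which were lower with 3 interferon and MHC lists (adjusted p 1.6e-05 to 0.019, and 0.6 to 0.77 with an estimated correlation). Ifi202b averaged 45.8 ± 3.47 CPM against no read in C57BL/6 (at least 154-fold higher) and Npy 45.8 ± 12.5 CPM against 1 read (1242-fold, interval 222 to 49080). Trim12a averaged 0.259 ± 0.0669 CPM against 167 ± 0.284 CPM (-7.79) and Vmn2r97 0.652 ± 0.536 CPM against 48.3 ± 9.51 CPM (-5.49), with Rps3a3 (5.87) and Hba-a2 (3 reads against 18865) uncertain. In all 1500 genes passed, 1030 higher and 470 lower in NZB/W-F1, 1507 in edgeR, 735 with only these libraries fitted and 788 without both libraries with pancreatic enzyme reads. Camera passed 13 lists, 0 with an estimated correlation, and fry 5. The 1500 became 2977, 864 and 839 without NZB/W-F1 replicates 1, 2 and 3 and 470 and 669 without C57BL/6 replicates 1 and 2. Elane missed the threshold without C57BL/6 replicate 1 (adjusted p = 0.083). The red pulp macrophage and iron list missed it without NZB/W-F1 replicate 2, or C57BL/6 replicate 1 (adjusted p 0.053 to 0.12). The erythroid list missed it without NZB/W-F1 replicate 1, or C57BL/6 replicate 2 (adjusted p 0.16 to 0.46). The erythroid list missed it with a block for replicate number (adjusted p = 0.056).

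From 1 to 3 months cell cycle and erythroid lists fell and plasma cell and antibody lists rose in the NZB/W-F1 spleen. In the cell cycle list 8 of 25 fell (25 adjusted over the list alone, median -1.79, adjusted p = 5.3e-13, adjusted p = 0.36 with an estimated correlation). In the erythroid list 3 of 18 fell (18 adjusted over the list alone, median -3.90, adjusted p = 4.9e-09, adjusted p = 0.36 with an estimated correlation). In the plasma cell list 7 of 15 rose (11 adjusted over the list alone, median 0.91, adjusted p = 9.0e-07, adjusted p = 0.17 with an estimated correlation). In the immunoglobulin constant list 7 of 12 rose (9 adjusted over the list alone, median 1.49, adjusted p = 2.1e-06, adjusted p = 0.058 with an estimated correlation). Ighg3 rose from 127 ± 84.3 CPM to 1527 ± 547 CPM (log2 fold change 3.84, SE 0.57, adjusted p = 0.016). The 3-month replicate 2 held 160100 CPM of pancreatic enzyme genes, the 1-month libraries 13.6 to 19.2, and without both libraries with such reads 1211 genes passed. The GABA receptor subunit Gabra4 (ENSMUSG00000029211, chromosome 5, 71569749 to 71658308) rose (log2 fold change 2.45, SE 0.69, adjusted p = 0.043). Ypel4 (ENSMUSG00000034059) (log2 fold change -4.60, SE 1.24, adjusted p = 0.039) and Ccdc92b (ENSMUSG00000069814) (log2 fold change -4.47, SE 1.31, adjusted p = 0.049) fell. The haemoglobin gene Hbb-bt (-4.33) fell but shares 59.4% of its words with another gene. In all 1388 genes passed, 654 higher and 734 lower at 3 months, and 1074 in edgeR, with a split of 498 and 892 under median-of-ratios scaling. Camera passed 18 lists, 0 with an estimated correlation, and fry 10. The 1388 became 35 and 538 without 3-month replicates 1 and 3 and 5, 6 and 32 without 1-month replicates 1, 2 and 3. Ighg3 missed the threshold without 1-month replicate 2 (adjusted p = 0.054). Gabra4 missed it without 3-month replicate 1 or 2, or 1-month replicate 1, 2 or 3 (adjusted p 0.061 to 0.14). Ypel4, Ccdc92b and Hbb-bt missed it without 3-month replicate 1 or 3, or 1-month replicate 1, 2 or 3 (adjusted p 0.064 to 0.16). Gabra4 missed it with only these libraries fitted (adjusted p = 0.11). Ypel4 and Ccdc92b missed it in edgeR (adjusted p 0.092 to 0.12). Ccdc92b missed it with a pseudocount of 0.1 (adjusted p = 0.052). In spleen 378 genes differed between the strains in 1 direction at all 3 ages, 251 higher and 127 lower in NZB/W-F1, against 5.46 and 0.986 expected of independent lists.

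In brain at 6 months markers of striatal neurons and endothelium, MHC class I genes and a microglial receptor gene were lower in NZB/W-F1 than in C57BL/6. Of the striatal neuron genes 7 of 12 fell (11 adjusted over the list alone, median -0.91, adjusted p = 1.9e-09, adjusted p = 0.46 with an estimated correlation), with the sodium channel subunit Scn4b at -0.94 (adjusted p = 0.0077). The striatal median from 3 to 6 months was -0.05 in NZB/W-F1 and 0.60 in C57BL/6. Choroid plexus and hypothalamic and pituitary hormone lists had medians of -0.37 and 0.59 (adjusted p = 0.14 and 0.55). C57BL/6 replicate 3 stood apart (chi-square per gene 35.1 and 41.1 from the others, 3.92 between these). Of the MHC class I genes 4 of 10 fell (4 adjusted over the list alone, median -0.28, adjusted p = 0.0049, adjusted p = 0.46 with an estimated correlation), with H2-T22 (-1.26, adjusted p = 2.6e-06) and H2-T23 (-1.43, adjusted p = 5.8e-04). Fcrls (ENSMUSG00000015852, chromosome 3, 87250758 to 87263738), a receptor-like gene of resident microglia, averaged 4.42 ± 0.856 CPM against 32.1 ± 0.929 CPM (log2 fold change -2.74, SE 0.18, adjusted p = 4.5e-09). In the endothelial list 2 of 13 fell (7 adjusted over the list alone, median -0.46, adjusted p = 1.3e-04, adjusted p = 0.46 with an estimated correlation). Scn4b missed the threshold without NZB/W-F1 replicate 1, or C57BL/6 replicate 2 (adjusted p 0.057 to 0.059).

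Among single genes of the 6-month brain, the phospholipase gene Pla2g4e (ENSMUSG00000050211, chromosome 2, 120166412 to 120245335) was higher at 44.1 ± 5.47 CPM against 6.15 ± 2.6 CPM (log2 fold change 2.81, SE 0.24, adjusted p = 2.2e-07). Myoc (ENSMUSG00000026697, chromosome 1, 162639155 to 162649693), the extracellular protein myocilin, was lower at 2.90 ± 1.41 CPM against 45.1 ± 5.63 CPM (log2 fold change -3.82, SE 0.23, adjusted p = 1.8e-09). The securin gene Pttg1 (ENSMUSG00000020415, chromosome 11, 43420250 to 43426251), which restrains chromosome separation, was lower (log2 fold change -3.60, SE 0.19, adjusted p = 2.6e-10). So was Tnni1 (ENSMUSG00000026418), slow muscle troponin I (log2 fold change -2.80, SE 0.23, adjusted p = 1.3e-07). The lens filament gene Bfsp2 (-2.83), Eps8l1 (-2.98) and Tceanc2 (-1.94), which overlaps the abundant Tmem59 on the opposite strand, were also lower. Near-identical copies leave Ndufs5 (ENSMUSG00000028648, chromosome 4, 123712710 to 123718202), a subunit of mitochondrial complex I (-3.15), Rps3a3 (5.37), Eno1b (5.14), Tpm3-rs7 (4.48), AK157302 (3.60), Hmga1b (3.01) and Eif3j2 (2.74) uncertain. In the 6-month brain 647 of 14895 genes passed, 315 higher and 332 lower in NZB/W-F1, 663 in edgeR and 380 with only these 6 libraries fitted. Camera passed 6 of 29 lists, 0 with an estimated correlation, and fry 4. The 647 became 428 without NZB/W-F1 replicate 1.

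The lower MHC class I signal of NZB/W-F1 brain, from sequence or expression, was present at 1 month. There 6 of 10 fell (6 adjusted over the list alone, median -0.74, adjusted p = 1.0e-06, adjusted p = 0.12 with an estimated correlation). H2-T23 stood at -1.56. At 3 months 4 of 10 fell (5 adjusted over the list alone, median -0.38, adjusted p = 4.7e-05, adjusted p = 0.29 with an estimated correlation), with H2-T23 at -1.51. At 1 month heat shock genes were higher, where 3 of 13 rose (3 adjusted over the list alone, median 0.43, adjusted p = 3.5e-04, adjusted p = 0.4 with an estimated correlation), with Hspa5 (1.15, adjusted p = 1.4e-04). The largest changes at 1 and 3 months were those of Pttg1 (-3.54 and -3.5), Tnni1 at 1 month (-3.00), Myoc at 3 months (-2.94) and, uncertain for their copies, Ndufs5 (-3.28 and -3.15), Eno1b (5.29 and 5.22), Rps3a3 (5.02 and 5.15) and Tpm3-rs7 (4.28 and 4.16). At 1 month 894 genes passed, 453 higher and 441 lower in NZB/W-F1, 756 in edgeR, and at 3 months 579, 290 higher and 289 lower, 634 in edgeR. Camera passed 5 and 2 lists, 0 and 0 with an estimated correlation, and fry 2 and 1. The 894 became 591 without C57BL/6 replicate 3. In brain 336 genes differed in 1 direction at all 3 ages, 186 higher and 150 lower in NZB/W-F1, against 0.187 and 0.191 expected of independent lists.

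From 1 to 3 months myelin genes fell in NZB/W-F1 brain: 7 of 15 fell (11 adjusted over the list alone, median -0.86, adjusted p = 1.1e-24, adjusted p = 0.02 with an estimated correlation). Mog, a myelin surface protein, fell from 239 ± 41.5 CPM to 103 ± 13.2 CPM (log2 fold change -1.21, SE 0.15, adjusted p = 6.0e-04). Cldn11, of the tight junctions in myelin, fell from 530.3 ± 94.9 CPM to 217 ± 48.3 CPM (log2 fold change -1.30, SE 0.17, adjusted p = 9.7e-04). In C57BL/6, a change that was not tested, Mog averaged 223 ± 34.8 CPM at 1 month and 108 ± 19.0 CPM at 3 months. Among genes of oligodendrocyte precursors and newly formed oligodendrocytes 2 of 12 fell (7 adjusted over the list alone, median -0.43, adjusted p = 3.2e-12, adjusted p = 0.0032 with an estimated correlation), with Gpr17 (-1.37, adjusted p = 2.5e-04). Il33 (ENSMUSG00000024810, chromosome 19, 29925114 to 29960718), an alarmin cytokine, rose from 19.8 ± 3.68 CPM to 60.8 ± 4.72 CPM (log2 fold change 1.61, SE 0.15, adjusted p = 6.3e-05). Abca8a (ENSMUSG00000041828), a lipid transporter, rose too (log2 fold change 1.75, SE 0.21, adjusted p = 6.0e-04), as did the antiviral protein gene Zc3hav1 (ENSMUSG00000029826) (log2 fold change 0.77, SE 0.15, adjusted p = 0.027). Of the interferon-stimulated genes 1 of 26 rose (4 adjusted over the list alone, median 0.36, adjusted p = 1.0e-09, adjusted p = 0.016 with an estimated correlation). The fibrillar collagen gene Col3a1 (ENSMUSG00000026043, chromosome 1, 45311538 to 45349706) fell (log2 fold change -1.41, SE 0.24, adjusted p = 0.012). The haemoglobin genes Hba-a1 (-2.29) and Hbb-bs (-2.13) fell with the erythroid list, where 2 of 6 fell (4 adjusted over the list alone, median -1.20, adjusted p = 1.7e-06, adjusted p = 0.048 with an estimated correlation). Both share most of their words with another gene. In all 41 genes passed, 7 higher and 34 lower at 3 months, and 31 in edgeR, while camera passed 9 lists, 4 with an estimated correlation, and fry 5. The 41 became 13 and 20 without 3-month replicates 2 and 3 and 18, 27 and 25 without 1-month replicates 1, 2 and 3. Zc3hav1 missed the threshold without 3-month replicate 2 or 3, or 1-month replicate 1, 2 or 3 (adjusted p 0.057 to 0.21). Col3a1 missed it without 3-month replicate 2 or 3, or 1-month replicate 1 or 2 (adjusted p 0.063 to 0.1). Hba-a1 and Hbb-bs missed it without any 1 of the 6 libraries (adjusted p 0.058 to 0.21). Zc3hav1 missed it with only these libraries fitted (adjusted p = 0.17). Zc3hav1, Hba-a1 and Hbb-bs missed it in edgeR (adjusted p 0.053 to 0.061).

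**Figure D5:**
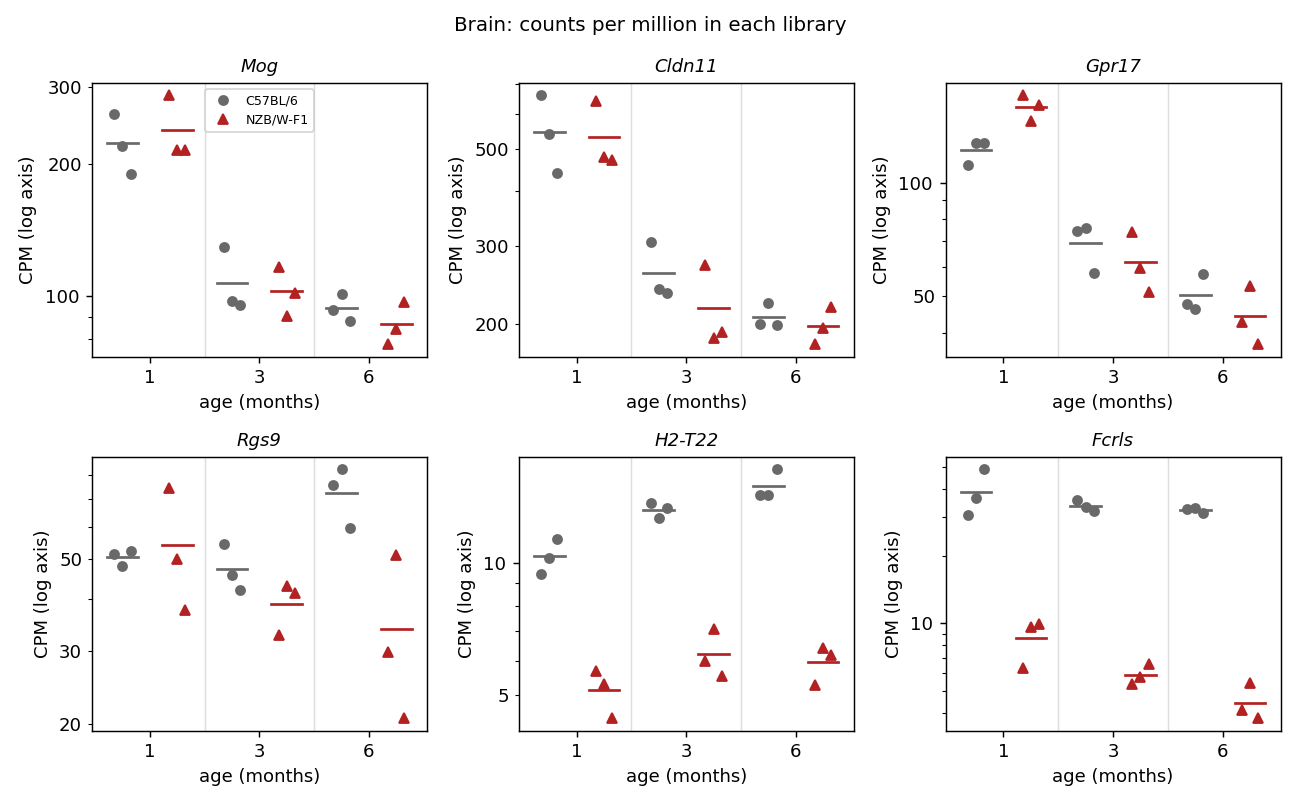
CPM (log axis) of Mog, Cldn11, Gpr17, Rgs9, H2-T22 and Fcrls in each brain library by age in months, as circles for C57BL/6 and triangles for NZB/W-F1, with a bar at each group mean. Mog stood at 239 ± 41.5 CPM in NZB/W-F1 at 1 month and at 103 ± 13.2 CPM at 3 months, and Fcrls was lower in NZB/W-F1 than in C57BL/6 at each age.

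From 3 to 6 months the NZB/W-F1 brain changed in 1 gene, Gabra6 (ENSMUSG00000020428, chromosome 11, 42306437 to 42321072), a GABA receptor subunit of cerebellar granule cells, which fell from 76.1 ± 18.5 CPM to 27.7 ± 4.87 CPM (log2 fold change -1.43, SE 0.21, adjusted p = 0.032). It was also the single gene in edgeR (1), 634 genes had an unadjusted p under 0.05, and 0 passed with only these 6 libraries fitted or with a block for replicate number. Of the cerebellar neuron genes 1 of 12 fell (8 adjusted over the list alone, median -0.66, adjusted p = 6.6e-17, adjusted p = 0.092 with an estimated correlation). The 1 became 0 without 6-month replicate 3 or any 3-month replicate. Gabra6 missed the threshold without any 1 of the 6 libraries (adjusted p 0.065 to 0.42). Gabra6 missed it with only these libraries fitted (adjusted p = 0.15) and with the block (adjusted p = 0.075). Over this interval C57BL/6 brain gave 0 genes in limma, 0 in edgeR and 986 at an unadjusted p under 0.05, with the striatal neuron list higher (median 0.60, adjusted p = 2.9e-08 and 0.9 with an estimated correlation) and the cerebellar neuron list lower there too (median -0.34, adjusted p = 8.0e-04 and 0.9 with an estimated correlation). For the strain by age interaction limma gave 0 genes, edgeR 0, and 416 had an unadjusted p under 0.05. Its striatal neuron list had median -0.74, adjusted p = 9.5e-10 and 0.74 with an estimated correlation, and its cerebellar neuron list median -0.42, adjusted p = 9.2e-04 and 0.74 with an estimated correlation. In C57BL/6 the cerebellar neuron list missed the threshold without 6-month replicate 2, or 3-month replicate 3 (adjusted p 0.077 to 0.13). In the interaction it did so without C57BL/6 6-month replicate 3 or 3-month replicate 2 (adjusted p 0.17 to 0.2).

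Some strain differences at 6 months were shared by the 3 tissues: 126 of 11983 genes tested in all passed in 1 direction in kidney, spleen and brain, 96 higher and 30 lower in NZB/W-F1, where 0.152 and 0.0264 would be expected of independent lists. By the codes in the sample descriptions the tissues came from the same animals, so the lists are not independent. Lower in all was Trim12a, which in brain had 2 reads against 117 (53.7-fold, interval 14.5 to 449). So were the tripartite-motif gene Trim30d (ENSMUSG00000057596, chromosome 7, 104470014 to 104507849), with log2 fold changes of -1.69, -3.95 and -2.13 in kidney, spleen and brain, and Tceanc2 with -2.89, -3.22 and -1.94. Ndufs5 (-3.36, -3.19 and -3.15) and the ribosomal protein gene Rpl26 (ENSMUSG00000060938, chromosome 11, 68901583 to 68906989) (-2.38, -2.80 and -1.91) were lower but are uncertain, since copies with 81.0% and 84.8% of their words in them were higher in all. Higher in all were Rps3a3, Eno1b, Tpm3-rs7, Hmga1b and Eif3j2, whose values are uncertain for their copies, as is the zinc finger gene Zfp984 among the lower. Of the shared genes that were higher, 75% had 50% or more of their 31-base words in a gene at another place, against 1.21% of other genes tested, and of those that were lower 16.7%. The 6-month NZB/W-F1 replicate 3 had almost no Xist reads in any tissue, and without it in all 3 tissues, an alternative chosen after seeing the data, 105 genes were shared.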

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

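Of 35 lists that camera passed for the interaction in the 3 tissues, the 5 kidney lists that fry passed too are given here, a limit set after the values were seen. In them the change from 3 to 6 months was larger in NZB/W-F1 than in C57BL/6, and what singled them out is that the difference itself was tested. Its median was 2.167 for immunoglobulin constant genes (adjusted p = 5.0e-04 by fry), 1.332 for B cell genes (0.0054), 1.121 for kidney injury genes (0.028), 0.986 for chemokines (0.038) and 0.525 for plasma cell genes (0.028), on the log2 scale. With an estimated correlation in camera, 0 of these lists passed. The 3-month levels are part of each difference. There the medians of NZB/W-F1 against C57BL/6 were -0.51, -0.31, -0.37, -0.54 and -0.23 in the same order, of which that of chemokines passed (adjusted p = 0.029). The chemokine list missed the threshold without NZB/W-F1 replicate 3, or C57BL/6 replicate 1 (adjusted p = 0.11).

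Genes named in a tissue were singled out where the strain difference had opposite signs at 2 ages in all libraries, a restriction to named genes that was also set after the values were seen. The difference was then tested in limma. In kidney the antibody gene Ighg2b differed by 3.732 between 6 and 3 months (adjusted p = 0.052). The coagulation cofactor Proz differed by -2.019 between 6 and 3 months (0.061) and -1.535 between 6 and 1 month (0.047). In spleen the cytokine receptor chain Il5ra differed by 2.376 between 6 and 3 months (0.074) and 2.564 between 6 and 1 month (0.0057). The GABA receptor subunit Gabra4 differed by 2.273 between 6 and 1 month (0.18) and 3.666 between 3 and 1 month (0.041), and the haemoglobin gene Hbb-bt, uncertain for its copies, by -3.942 between 3 and 1 month (0.11). In brain the antiviral gene Zc3hav1 differed by 0.572 between 3 and 1 month (0.83).

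At 6 months the proton pump gene Atp4a was lower in kidney and higher in spleen in NZB/W-F1, a gap of 5.161 between the 2 log2 fold changes that was not tested.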

How the results depend on the processing

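The numbers of genes past the threshold varied with the settings as follows, and the cause was not tested. Of 25 counts, 11 moved by over 1.5 times when only the compared groups were fitted. They became in kidney 2197 (strains at 1 month), 596 (strains at 3 months), 0 (NZB/W-F1 3 against 1 month), 78 (NZB/W-F1 6 against 3 months) and 0 (C57BL/6 6 against 3 months), in spleen 735 (strains at 3 months), 517 (strains at 6 months), 14 (NZB/W-F1 6 against 3 months) and 0 (C57BL/6 6 against 3 months), in brain 380 (strains at 6 months) and 0 (NZB/W-F1 6 against 3 months). A pseudocount of 0.1 gave 0 in kidney and 188 in spleen (C57BL/6 6 against 3 months), and 54 in spleen (NZB/W-F1 6 against 3 months). EdgeR gave 0 in kidney and 23 in spleen (C57BL/6 6 against 3 months). A block for replicate number gave 430 in spleen (C57BL/6 6 against 3 months) and 0 in brain (NZB/W-F1 6 against 3 months). Median-of-ratios scaling and no filter moved 0 of the 25. Of alternatives added after seeing the data, the crossed numbering of the spleen replicates gave 222 (C57BL/6 6 against 3 months), and without both libraries with pancreatic enzyme reads there were in spleen 2044 (strains at 1 month), 788 (strains at 3 months) and 39 (NZB/W-F1 6 against 3 months).

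Leaving out each replicate in turn moved 68 of 207 counts. Kidney counts ranged over 2090 to 3552 (strains at 1 month), 809 to 4218 (strains at 3 months), 488 to 750 (strains at 6 months), 17 to 227 (NZB/W-F1 3 against 1 month), 108 to 290 (NZB/W-F1 6 against 3 months), 0 to 1780 (C57BL/6 6 against 3 months) and 0 to 2839 (strain by age). Spleen counts ranged over 1864 to 4852 (strains at 1 month), 470 to 2977 (strains at 3 months), 392 to 727 (strains at 6 months), 5 to 1615 (NZB/W-F1 3 against 1 month), 28 to 66 (NZB/W-F1 6 against 3 months), 0 to 318 (C57BL/6 6 against 3 months) and 0 to 171 (strain by age). Brain counts ranged over 591 to 684 (strains at 1 month), 400 to 616 (strains at 3 months), 428 to 581 (strains at 6 months), 13 to 60 (NZB/W-F1 3 against 1 month), 0 to 1 (NZB/W-F1 6 against 3 months), 0 (C57BL/6 6 against 3 months) and 0 (strain by age). Genes differing at all 3 ages ranged over 309 to 389 in kidney, 278 to 414 in spleen and 295 to 324 in brain, and those shared by the 3 tissues over 103 to 124. The direction of the test turned for some lists in NZB/W-F1 from 3 to 6 months, with these medians. In kidney it was extracellular matrix (-0.108 without 6-month replicate 2, range over left-out replicates -0.108 to 0.628). In spleen they were B cell (0.023 without 3-month replicate 1 and 0.126 without 6-month replicate 2, range -0.398 to 0.126), neutrophil (-0.003 without 3-month replicate 3, range -1.18 to -0.003) and cell cycle (-0.153 without 6-month replicate 2, range -0.153 to 0.922).

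Of 204 list calls, 9 were lost in edgeR, 5 with only the compared groups, 3 with the block, 2 with the pseudocount, 1 with median-of-ratios scaling and 0 without the filter. Of 185 calls of named genes, 26 were lost with only the compared groups, 14 in edgeR, 7 with the pseudocount, 2 with the block and 0 with median-of-ratios scaling. Left-out replicates ended 154 of 1345 list calls and 118 of 1063 gene calls.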

Other observations

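The tests of 1 X chromosome and of a wrong strain label in the first of the next 3 patterns, those of reference alleles in the second and both tests of the third were chosen after the result was seen. The 6-month NZB/W-F1 replicate 3 held 1.38, 1.44 and 0.857 CPM of Xist, the RNA that silences the second X chromosome, in kidney, spleen and brain, where all other libraries held 274 to 1712. Male-biased kidney genes had a median difference of 0.078 from the other NZB/W-F1 libraries (log2, others -0.33 to 0.42), which argues against a male animal. In fits without this animal, at most 3.881% of genes differing between strains at all ages lay nearer to C57BL/6 in it (other NZB/W-F1 at most 5.62%, C57BL/6 at least 94.97%), and at most 34.0% of those differing at 1 and 3 months (24.9% and 64.7%), which argues against a wrong strain label. This animal was the lowest NZB/W-F1 library in 10 of 18 pairs of gene and tissue for genes that escape X inactivation. A single active X without Xist may be a candidate explanation, and a cause other than a lost X stays open. No biological explanation is given by the design.

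Of the 96 genes higher in NZB/W-F1 in all 3 tissues at 6 months, 75% had 50% or more of their words in a gene at another place, against 1.21% of other genes (Fisher exact p = 7.2e-109, two-sided). So had 16.667% of the 30 lower ones (Fisher exact p = 2.0e-04). Of 68 such genes with a partner tested in kidney, the partner was called there in the opposite direction in 17 and in the same one in 4. Reads of strain-specific alleles that align to a copy may be the source of many of these calls. The 96 higher genes stood 0.81 or more above C57BL/6 (mean log2), past the largest median of all genes (0.04). They were chosen as higher, so this cannot test a better alignment of reference alleles. It stays open for them and the 30 lower ones, as no table holds the alleles. Strain differences in sequence and in expression were not separated here or for MHC class I or antibody genes.

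Immune lists rose from 3 to 6 months in NZB/W-F1 kidneys. Of 6 kidneys with more haemoglobin RNA (Hbb-bs) than every 6-month NZB/W-F1 library, 0 reached that group's lowest macrophage list level. Only 1-month replicate 2 of them was NZB/W-F1, and copies leave Hbb-bs uncertain, so blood left in the vessels stays open. The macrophage median lay 1.376 above the higher of the endothelial and distal tubule medians (log2), which argues against less tubule in the pieces taken as the whole cause. In C57BL/6 the macrophage median was 0.20 (adjusted p = 0.061), and the interaction median 1.06 (adjusted p = 2.0e-05, 0.42 with an estimated correlation and 0.074 by fry). Age, and batch with it, was thus compared in part. Disease stage was not tested apart from age, and all stay open.

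Other splits of the same libraries were counted by how many called at least as many genes as the real one. With 3 against 3 libraries the 10 splits are too few for a share under 0.05. In kidney the numbers were 1 (strains at 1 month: real 3310, highest other 0), 1 (strains at 3 months: real 2177, highest other 678), 1 (strains at 6 months: real 818, highest other 0), 2 (NZB/W-F1 3 against 1 month: real 43, highest other 1143), 1 (NZB/W-F1 6 against 3 months: real 301, highest other 0) and 2 (C57BL/6 6 against 3 months: real 1, highest other 8). In spleen they were 1 (strains at 1 month: real 4449, highest other 0), 1 (NZB/W-F1 3 against 1 month: real 1388, highest other 2) and 1 (NZB/W-F1 6 against 3 months: real 86, highest other 2). In brain they were 1 (strains at 1 month: real 894, highest other 0), 2 (strains at 3 months: real 579, highest other 766), 1 (strains at 6 months: real 647, highest other 0), 1 (NZB/W-F1 3 against 1 month: real 41, highest other 1), 1 (NZB/W-F1 6 against 3 months: real 1, highest other 0) and 10 (C57BL/6 6 against 3 months: real 0, highest other 4177). The kidney split with 1143 genes set 3-month replicate 1 and 1-month replicates 1 and 2 against the others. The brain split with 4177 set 6-month replicates 1 and 2 and 3-month replicate 2 against the others: each points to a structure of the samples other than age. Among the 4 kidney splits that part all 3 same-number NZB/W-F1 pairs, the highest other gave 0. The split with 1143 kept pairs 1 and 3 and parted pair 2.

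Of 100 drawn assignments of strain within age, 1 in kidney and 1 in brain, the real one, gave as many genes differing at all 3 ages (382 and 336, highest others 0 and 0), which excludes chance for these counts. Of 100 assignments of age within strain, 100 and 100 gave at least the 0 genes of the interaction in kidney and brain (highest others 804 and 3129). By camera 33 and 67 gave at least as many lists (13 and 4, highest others 22 and 15), so chance was not excluded for the interaction lists of either tissue. The strain by age difference of 6 against 1 month gave 529 (range 180 to 1261), 148 (range 2 to 2362) and 5 (range 2 to 31), and that of 3 against 1 month 209 (range 73 to 2100), 1639 (range 0 to 2404) and 1 (range 0 to 2), in kidney, spleen and brain. The ranges are those without 1 library, and these intervals were not in the plan.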
